A study of Rattus norvegicus with 16 samples.

How the data were processed

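Frontal cortex of male Sprague-Dawley rats was profiled by RNA sequencing in 16 samples. Per the labels, about 1000 ng of total RNA was selected for poly-A RNA, fragmented, copied with random primers and sequenced on an Illumina HiSeq, from fragments of 200 to 400 bp. The strand is not given in the sources used here, so antisense and overlapping transcripts cannot be told from a gene's own. The deposited table holds FPKM (fragments per kilobase of transcript scaled to the mapped fragments) per merged locus and sample, as made by the authors, with a status of OK, FAIL or HIDATA for each value. The submitters' processing notes name TopHat, TopHat2, Bowtie, Bowtie2, Cufflinks, Cuffdiff and the rat build rn5, without versions or roles. The values were taken as deposited, and the table held 0 per-sample columns from outside this series.

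Samples were grouped by the treatment stated for each: chow diet, high fat diet, high fat diet with PBS, and high fat diet with 5-AzaD in PBS, 4 of each. The design text uses the letters HFD for the diet alone, whereas the sample titles give them to the PBS animals; the groups follow the stated treatment, and the comparisons of both injected groups with HF and with chow show what would be exchanged: the diet comparison would then hold 4173 calls and the inhibitor comparison 2112, in place of 0 and 0. Replicate numbers come from the titles. They gave no sign of pairing: correlations between same-numbered samples, after removing group means, were -0.164 to 0.0236 for chow and HF_PBS, where 0 of 4 matched best with their own number, and -0.107 to 0.0641 for HF and HF_5AzaD, where 0 of 3 did. So few correlations could miss a weak shared effect.

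The table holds 28168 loci, 18005 of them with a gene symbol, and 1404 symbols stand for several loci. Loci with a status other than OK in any sample (161, of which 136 pass the filter) were left out, a choice made after seeing the table. They include 1 locus of LOC310926, which has the status HIDATA only in the chow samples, and ribosomal RNA loci with that status in all 16. Loci with a mean of at least 1 FPKM over all samples were tested, 14824 in all. Group differences came from limma 3.58.1 in R 4.3.3 (linear models with a mean-dependent prior for the variance) on log2(FPKM + 0.5), with 1 mean per group over all 16 samples, 12 residual degrees of freedom and 6 contrasts. P-values were adjusted by Benjamini-Hochberg over the loci tested, and a locus passed at an adjusted p under 0.05. All p-values given for genes are adjusted ones from limma unless called unadjusted. Plots and the estimate of depth used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

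Gene lists were fixed before the data were examined: 41 lists of pathways, stress responses, cell types and neighbouring brain regions, of which 39 had at least 5 tested members. A symbol with several loci is represented by the locus with the highest mean, a choice made after seeing the table. Lists were tested with camera (limma), which compares a list with the other loci, with the correlation between its members estimated from the residuals. Camera with a preset correlation of 0.01 and fry, which asks whether a list's members move one way on balance, were run beside it. Members past the gene test were counted over all loci and also adjusted over the list alone. Lists share some genes, and most members of the lists for other regions and cell types are also measured in cortex. A list score is the mean over its members of the log2 value less that member's mean over the 16 samples. Group differences in 3 scores were tested by a two-sided exact permutation test.

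Genes named in the text follow a rule fixed before the data were examined. In HF against chow and in HF_5AzaD against HF_PBS these are the 10 largest changes per direction among called genes whose groups do not overlap or, as happened here, the 5 with the lowest p and non-overlapping groups per direction, given as not past the test. In the other 4 comparisons they are the 5 largest called changes per direction with non-overlapping groups. Only the locus with the highest mean of each symbol was ranked, a limit chosen after seeing the table, and the lesser loci of Pja2 and Nlk are given as examples chosen after their values were seen. Dnmt1, Dnmt3a, Bdnf, Fos, Arc, Fkbp5 and Cdkn1a are given throughout; Tet1, Tet2 and Tet3 were on the same list but were not among the loci tested. A few other genes are not reported here. For the 4 comparisons with calls, list examples are mostly the called members with the lowest p, and other members, as well as all list examples in the 2 comparisons without calls (such as Mbp and Drd2), were chosen after their values were seen. The genes followed across alternatives in those 4 comparisons are the named ones past the test and up to 3 called members per list.

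Fold changes of pairs of comparisons were correlated across loci, with p-values from 100 regroupings of the samples within each pair of groups and, where chow was shared, from simulated groups with no change. The analysis was tested on simulated data, drawn independently for each locus from its mean and residual SD, with 200 loci changed by 1.5-, 2- or 4-fold. Such values lack the correlation between loci and the outlying samples of the real data, so recovery there may differ. Of 161 loci called in the simulated HF and chow groups 13 were false, as were 13 of 158 in the simulated HF_5AzaD and HF_PBS groups.

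Depth per sample is unknown in reads. A relative depth was estimated from 7165 low loci (at most 0.5 FPKM), in which values of 2 samples should stand in ratios of small whole numbers (up to 5) times a constant; 41.3% of ratios lay within 0.01 log2 of such a value, against 4.16% when shifted by 0.05. The sum of FPKM differed widely between samples, with 14.0% to 76.5% of it in a single locus. The status HIDATA applied to 6 loci in each chow sample and to 4 in each of the others.

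Alternatives chosen before the data were examined were a pseudocount of 0.1 or 1, no filter or a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, a fit of 2 groups only, sample weights, robust variance estimates, an adjusted p under 0.10, a block for the replicate number, each sample left out in turn, and the other list tests. Chosen after seeing the data were keeping loci of every status, 1 locus per symbol, leaving out the samples with a score above 0.8 on the thalamus and subcortical list (HF_PBS 3 and 4) or on the striatum list (HF 8 and HF_PBS 2, 3 and 4), both scores as covariates, and following single lists and genes through all of these in the 4 comparisons with calls. Gene coordinates, length and base composition were not used here, since the reference at hand belongs to another build. Other material of the study was not analysed here.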

Results

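RNA was measured by poly-A RNA sequencing in the frontal cortex of male Sprague-Dawley rats, in 16 libraries that form 4 groups of 4. The chow group ate a chow diet and the HF group a high fat diet, each for 7 weeks from an age of 11 weeks. Rats of the HF_PBS group ate the high fat diet and were injected with saline buffer (PBS) into the abdomen for 10 days. Rats of the HF_5AzaD group ate the same diet and were injected for 10 days with 5-AzaD (5-aza-2′-deoxycytidine), an inhibitor of DNA methyltransferases, in PBS. Values are FPKM per locus as deposited, and group values are mean ± SD of 4 libraries. Fold changes are on the scale of log2(FPKM + 0.5), which understates changes of genes near the floor. Nothing in the labels says that the libraries of a group come from separate animals, so p-values measure only the spread between these samples, which may be technical.

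Read counts per library were not used here, and the absolute depth is unknown. The steps between the lowest FPKM values give a relative depth: with chow 2 as 100%, the other chow libraries had 63.3%, 38.7% and 54.6%. The HF libraries 5 to 8 had 36.5%, 30.1%, 32.1% and 31.3%, the HF_PBS libraries 1 to 4 had 42.5%, 32.6%, 36.7% and 35.7%, and the HF_5AzaD libraries 3, 5, 6 and 7 had 44.4%, 40.3%, 38.7% and 34.7%. Between 23064 and 24333 loci were above 0 in a library, and 14824 loci were tested, 11033 of them with a gene symbol. Pairs of libraries correlated between 0.862 and 0.984.

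The first question was what the diet alone did, in HF against chow. No gene passed the test. Tsc22d3, a gene induced by glucocorticoids, was at 52.9 ± 2.29 FPKM in chow and 34.8 ± 3.56 in HF, a log2 difference of -0.60 (SE 0.143, adjusted p = 0.682). Nfil3, a transcription factor of the circadian clock, was at 9.49 ± 1.55 and 5.81 ± 1.14, a difference of -0.67 (SE 0.131). In all 4 HF libraries both genes lay below every chow library, as did Pip5k1b (19.9 ± 2.77 and 10.3 ± 2.54), the secretory granule protein gene Chga (113 ± 6.41 and 88.2 ± 5.95) and Arl5b (6.4 ± 0.839 and 4.27 ± 0.467). All 4 HF libraries lay above every chow library for the collagen gene Col5a2 (2.20 ± 0.318 and 4.52 ± 1.45), Agrn (23.4 ± 2.48 and 31.1 ± 2.31), the G protein subunit gene Gnb4 (2.31 ± 0.726 and 5.01 ± 1.52), Ndor1 (7.38 ± 1.06 and 10.7 ± 1.27) and the kinase gene Rock1 (6.30 ± 1.34 and 10.4 ± 2.06). Each of these 10 genes had an adjusted p of 0.682.

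The glucocorticoid response genes lay lower in HF on balance: 4 of 19 measured members were above chow, with a median log2 difference of -0.35. None passed the test over all genes, and 2 were lower when adjusted over the list alone. Besides Tsc22d3, Errfi1 was at 14.0 ± 1.52 in chow and 9.43 ± 0.944 in HF, and the clock gene Per1 at 25.9 ± 6.77 and 16.1 ± 7.13. The list had an adjusted p of 0.00122 with the preset correlation, and adjusted p = 0.805 with an estimated correlation (unadjusted 0.0487). All 21 microglia markers were higher in HF, with a median of 0.23 and no call. Among them, the receptor genes Cx3cr1 (11.3 ± 0.281 and 16.1 ± 1.98) and Csf1r (16.7 and 23.0) had adjusted p of 0.706 and 0.727, and the list had 0.00138 preset and adjusted p = 0.805 with an estimated correlation. Of 69 nuclear-encoded respiratory chain subunits 3 were higher and none passed, with a median of -0.15, as for Cox7b (169 and 134) and Cycs (29.2 and 21.2). That list had 1.66e-06 preset and adjusted p = 0.806 with an estimated correlation.

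Immediate early genes, which report recent neuronal activity, had 5 of 19 members higher in HF and a median of -0.33 (0.00951 preset, adjusted p = 0.805 with an estimated correlation). Fos was at 26.4 ± 12.2 in chow and 12 ± 12.2 in HF, a difference of -1.40 with a 95% interval of -2.63 to -0.17 (adjusted p = 0.696), and Arc at 95 ± 42.4 and 42.9 ± 34.1 (-1.33, adjusted p = 0.696). Deep cortical layer markers had 11 of 12 members higher (median 0.35, 0.0471 preset, adjusted p = 0.805 with an estimated correlation), among them Bcl11b (6.63 and 11.4) and Sulf2 (31.7 and 42.7). The deep layer score was 0.432, -0.0101, -0.24 and 0.501 in HF 5 to 8 and -0.592 to 0.148 in chow, so HF 6 and 7 lay inside the chow range. All 8 upper cortical layer markers were lower (median -0.25), such as Rorb (17.8 and 9.17). Endoplasmic reticulum stress genes (1 of 19 higher, 0.0272 preset) and heat shock and cold response genes (4 of 16 higher, 0.0498 preset) both had adjusted p = 0.805 with an estimated correlation. Of 16 circadian clock genes, 6 were higher, and Nfil3 was lower when adjusted over the list alone. Of 14 neurotrophin and plasticity genes, 10 were higher, and Ntrk3 (18.4 and 26.4) was so when adjusted over the list alone.

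Genes of fat handling differed little: 18 of 23 cholesterol synthesis genes (median 0.06) and 12 of 17 fatty acid synthesis genes (median 0.10) were higher, with no call in either list. PPAR targets and fatty acid oxidation genes had a median of -0.0335, a mean of 0.0128 and an upward test, so these differ in sign. The writers and readers of DNA methylation were near level. Dnmt1 was at 7.24 and 7.51 (adjusted p = 0.928), Dnmt3a at 7.09 and 6.53 (0.799), Bdnf at 5.59 and 6.01 (0.987), the glucocorticoid target Fkbp5 at 14.8 and 15.8 (0.943) and the cell cycle inhibitor Cdkn1a at 7.40 and 6.37 (0.874). The 14 measured genes of the DNA methylation list had a median of -0.03 (adjusted p = 0.95).

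Limma called 0 of 14824 loci, with 1020 at an unadjusted p under 0.05 (470 higher and 550 lower) and a lowest adjusted p of 0.682. The groups lay fully apart in 6.95% of loci, against 2.86% by chance. Relative depth lay fully apart as well, at 30.1% to 36.5% in HF and 38.7% to 100% in chow. Whether depth affected this share was not tested. No list passed with an estimated correlation (1 of 39 at an unadjusted p under 0.05), 7 passed with the preset correlation and fry called 0 (1 unadjusted). HF 8 held far more striatal RNA than the rest of its group, with a striatum score of 2.16 against -0.474 to -0.325 in the other HF libraries, and 12 of 16 striatum markers were higher in HF (median 0.51, none called). On simulated values, drawn independently for each locus with its spread in these data, the test recovered 47.8%, 76.1% and 98.5% of genes set 1.5-, 2- and 4-fold apart in this comparison. These values lack the correlation between genes and outlying libraries such as HF 8, so recovery in the real data may differ. The letters HFD mean the diet-only group in the design text but the PBS animals in the titles; were HF and HF_PBS exchanged, this comparison would hold the 4173 calls of HF_PBS against chow.

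The second question was what 5-AzaD did beyond its vehicle, in HF_5AzaD against HF_PBS. No gene passed the test here either. The cadherin gene Cdh22 came nearest, at 10.6 ± 0.943 in HF_PBS and 18.4 ± 2.38 in HF_5AzaD, a log2 difference of 0.76 (SE 0.121, adjusted p = 0.237). Neurod1, a neuronal transcription factor, was at 3.27 ± 1.32 and 7.15 ± 1.74 (1.07), Plxnd1, a semaphorin receptor, at 6.43 ± 2.00 and 13.4 ± 3.95 (1.00), Gal3st3 at 22.7 ± 5.36 and 42.4 ± 12.7 (0.87), and Rreb1 at 1.41 ± 0.472 and 3.03 ± 0.433 (0.91). Lower in every HF_5AzaD library than in any HF_PBS library were Grm3, a glutamate receptor gene (26.4 ± 4.49 and 15.6 ± 3.94, -0.76), Pon2 (56.6 and 37.1, -0.58), Spg20 (11.4 and 8.41, -0.40), the cohesin gene Rad21 (36.6 ± 1.84 and 30.4 ± 1.59, -0.26) and the neuropeptide gene Gal (14.9 ± 16.4 and 0.989 ± 0.389, -2.58). These 9 had an adjusted p of 0.586. Gal was at 2.96, 1.85, 37.0 and 18.0 FPKM in HF_PBS 1 to 4, so much of its difference rests on HF_PBS 3 and 4.

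Myelin genes had lower means in HF_5AzaD, with no call. All 25 measured oligodendrocyte and myelin genes had a negative difference (median -0.88), such as Enpp2 (83.4 ± 27.0 and 42.9 ± 14.1, -0.94), Cldn11 (273 ± 129 and 124 ± 43.5, -1.05) and Mbp (5600 ± 3510 and 2670 ± 1440). None passed over all genes, and 18 were lower when adjusted over the list alone. The list had 1.62e-22 with the preset correlation and adjusted p = 0.473 with an estimated correlation (unadjusted 0.0350), its members sharing a residual correlation of 0.901. All 16 striatum markers were lower too (median -1.2, 0 when adjusted over the list alone). The dopamine receptor gene Drd2 was at 10.3 ± 6.03 and 1.08 ± 0.271 (-2.40), the adenosine receptor gene Adora2a at 21.9 ± 13.3 and 2.77 ± 1.30, Rgs9 at 29.2 ± 20.9 and 3.57 ± 1.68, and the tachykinin gene Tac1 at 52.8 ± 27.8 and 12.3 ± 6.58. The striatum list had 5.8e-10 preset and adjusted p = 0.492 with an estimated correlation. Its score was 0.643 ± 0.851 in HF_PBS and -0.651 ± 0.138 in HF_5AzaD (two-sided exact permutation p = 0.0857, 0.257 adjusted over 3 scores, n = 4), and the myelin score 0.577 ± 0.774 and -0.293 ± 0.521 (two-sided exact permutation p = 0.2, adjusted 0.3, the smallest possible being 0.0286). The myelin score was 0.393, -0.443, 1.2 and 1.16 in HF_PBS 1 to 4 and -0.368, -0.832, 0.42 and -0.391 in HF_5AzaD 3, 5, 6 and 7, so that only HF_PBS 3 and 4 lay above all HF_5AzaD libraries.

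Cortical neuron markers went different ways. Deep cortical layer markers had 2 of 12 members higher in HF_5AzaD and a median of -0.545 (1 lower when adjusted over the list alone, 0.000434 preset, adjusted p = 0.473 with an estimated correlation), for example Tle4 (18.4 and 11.8) and Syt6 (7.79 and 3.68). GABAergic interneuron genes had 3 of 15 higher (0.00455 preset, adjusted p = 0.473 with an estimated correlation), among them Crh at 7.63 and 4.92. Excitatory neuron and glutamate synapse genes had 23 of 24 higher, with a median of 0.26 (0.000435 preset, adjusted p = 0.877 with an estimated correlation), such as Gria4 (31.8 and 39.9) and Camk2a (714 and 1002). Astrocyte markers had 5 of 18 higher, with Gfap at 196 and 122.

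Lists chosen for a loss of DNA methylation showed no shift past the test. The DNA methylation machinery had 6 of 14 members higher and a median of -0.01 (adjusted p = 0.924), with Dnmt1 at 6.24 and 6.16 (adjusted p = 0.987) and Dnmt3a at 5.39 and 5.82 (0.870). Imprinted genes had 9 of 17 higher (adjusted p = 0.925), and genes of nucleoside uptake and 5-AzaD metabolism 5 of 12 (0.924). Of 18 germline genes that methylation silences in other tissues, 13 were present and none exceeded a mean of 0.488 FPKM over all libraries, so the list was not tested. MHC class I and antigen presentation genes had 7 of 13 higher, a median of 0.15 and a mean of 0.386 (adjusted p = 0.918). RT1-A1, a class I heavy chain gene, was at 22.6 ± 13 and 91.4 ± 56.2 (1.92, adjusted p = 0.610). Genes of p53 and DNA damage split 10 and 10 with a median of 0.00662, a mean of -0.033 and a downward test, which differ in sign, and Cdkn1a was at 10.6 and 8.78 (adjusted p = 0.849). Interferon response genes had 17 of 25 higher. Bdnf was at 6.76 and 6.39 (0.997), Fos at 20.5 and 18.9 (0.952), Arc at 68.8 and 67.8 (0.959) and Fkbp5 at 11.7 and 12.9 (0.916).

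Limma called 0 loci, with 1100 at an unadjusted p under 0.05 (540 higher and 560 lower), and the groups lay fully apart in 2.40% of loci, against 2.86% by chance. No list passed with an estimated correlation (3 of 39 unadjusted), 10 passed with the preset correlation and fry called 0 (5 unadjusted). Without HF_5AzaD 7, 1 locus passed. On values simulated in the same way, with the same limits, the test recovered 40.3%, 85.1% and 92.4% of 1.5-, 2- and 4-fold changes in this comparison. Were HF and HF_PBS exchanged, it would hold the 2112 calls of HF_5AzaD against HF.

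The third comparison, HF_PBS against HF, asks about the vehicle injections on the high fat diet. In every comparison of an injected with an uninjected group, a library or sequencing batch that follows the injections, if there was one, cannot be told apart from them. Some genes of protein synthesis and respiration rose and some of glutamate synapses and insulin signalling fell, while no list passed with an estimated correlation. Ribosomal protein transcripts rose in 31 of 61 measured members and fell in 0, among them Rpl6 (4.87 to 10.5 FPKM), Rpl10a (6.71 to 17.8), Rps15a (6.90 to 17.5) and Rps24 (135 to 365, log2 1.42, adjusted p = 0.00354). Respiratory chain subunits rose in 31 of 69 and fell in 1, Sdha. Ndufv2 of complex I rose from 138 to 220 (0.67, adjusted p = 0.00270), Ndufa11 from 98.9 to 156 and Uqcrb of complex III from 14.3 to 27.2. When adjusted over the list alone, the counts were 36 up and 0 down for the ribosomal list, and 44 up and 1 down for the respiratory list. With the preset correlation these lists had 4.2e-10 and 8.5e-11, and each had adjusted p = 0.838 with an estimated correlation. Ribosomal protein genes have many processed copies, and reads that fit several of them make single values uncertain.

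Excitatory neuron and glutamate synapse genes fell in 7 of 24 members and rose in none (0 up and 7 down when adjusted over the list alone). The postsynaptic scaffold genes Shank1 (118 to 50.0, log2 -1.2), Shank2 (4.26 ± 2.75 to 0.718, -1.84, adjusted p = 0.00291) and Shank3 (50.8 to 27.5, -0.86) fell, as did the kinase gene Camk2a (1580 to 714, -1.17, SE 0.265, adjusted p = 0.00813). The list had 0.0014 preset and adjusted p = 0.838 with an estimated correlation. Insulin and energy sensing genes fell in 7 of 22 (1 up and 7 down when adjusted over the list alone), with Pdpk1 (32.4 to 20.1, -0.68), Tsc1 (12.9 to 8.52, -0.58) and Foxo3 (15 to 8.26, -0.81). Here fry gave 0.0477, the preset correlation 0.0586, and adjusted p = 0.838 with an estimated correlation. Monoamine, opioid and cannabinoid receptor genes fell in 5 of 20 (6 when adjusted over the list alone), among them Htr5a (4.35 to 2.26).

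Of the stress lists, glucocorticoid response genes rose in 6 of 19 members (7 when adjusted over the list alone), with Mt1a (4.15 to 9.59), Nfkbia (13.7 to 23.4), Pdk4 (1.55 to 5.30) and Tsc22d3 (34.8 to 48.7). Oxidative stress genes rose in 5 of 20 (9 when adjusted over the list alone, fry 0.0477), with Prdx1 (14.0 to 36.4) and Gstm1 (57.1 to 127). Heat shock and cold response genes rose in 4 of 16 and fell in 1, Hspa8 (4 and 1 when adjusted over the list alone), and endoplasmic reticulum stress genes rose in 3 of 19 (1 when adjusted over the list alone), namely Ddit3, Dnajb9 and Calr. Each of these lists had adjusted p = 0.838 with an estimated correlation. Of 14 genes of the DNA methylation machinery 3 rose and 6 fell (3 and 6 when adjusted over the list alone, adjusted p = 0.846 with an estimated correlation). The merged locus Fem1a,Uhrf1 fell from 16.2 to 9.71, Dnmt1 from 7.51 to 6.24 (-0.24, adjusted p = 0.0331) and Dnmt3a from 6.53 to 5.39 (-0.26, 0.0454), while Mbd2 rose from 21.3 to 26.6. After quantile normalization 3 members rose and 3 fell, and the calls of Dnmt1 (0.0858) and Dnmt3a (0.0857) ended; that of Dnmt3a also ended after median-ratio scaling (0.0501). Cholesterol synthesis genes fell in 5 of 23 and rose in 2 (the same counts when adjusted over the list alone), with the regulator gene Srebf2 (57.3 to 36.7) down and Idi1 (8.44 to 12.4) up. Clock genes fell in 3 of 16, with Clock (3.92 to 1.47), Cry2 (39.8 to 26.8) and Tef (75.2 to 50.4), and rose in 1, Nfil3 (5.81 to 8.27), the same counts as when adjusted over the list alone.

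Taking for each symbol its locus with the highest mean, the largest rises with groups fully apart were of the neuroendocrine gene Pcsk1n (0.222 ± 0.169 to 8.86 ± 7.05, log2 3.24, adjusted p = 0.00637), which chow libraries listed at 3.22, 6.88, 0.217 and 2.00, S100a11 (2.19 to 8.35, 1.73), Gnrh1 (0.227 to 3.71 ± 5.72, 1.73, but 0.91 without HF_PBS 3), the antigen presentation gene Cd74 (5.10 to 22.3 ± 19.8, 1.61) and Apod (135 ± 33.5 to 387 ± 169, 1.44, 0.0119). The largest falls by the same choice were of Gfod1 (31.2 ± 16.7 to 5.94 ± 2.87, -2.28, adjusted p = 0.00259), the sodium channel gene Scn1a (9.97 to 1.78, -2.12), Caln1 (31.4 to 6.79), the potassium channel gene Kcnh7 (9.19 to 1.58, -2.04) and the exocyst gene Exoc8 (adjusted p = 0.00408). Exoc8 was listed at 0 in 3 libraries of HF_PBS and at 2.39 in the other, and in HF at 4.33, 10.8, 4.67 and 6.43. Lesser loci of some symbols changed more, such as those of Pja2 (5.28) and Nlk (-3.83). Cdkn1a rose from 6.37 to 10.6 (0.66, adjusted p = 0.0477), and Fkbp5 (0.0836), Fos (0.166), Arc (0.238) and Bdnf (0.733) did not pass. Markers of other tissue moved with these groups: myelin genes rose in 5 of 25 (2 when adjusted over the list alone), such as Aspa (9.32 to 18.9), and the thalamus and subcortical score was 1.62 in HF_PBS 3 and 0.859 in HF_PBS 4, against -0.476 to -0.0475 in the HF libraries.

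Limma called 3536 loci, 1580 higher and 1956 lower (1260 and 1253 with a symbol), with 5619 at an unadjusted p under 0.05 and a median change of 1.49-fold among those called. No list passed with an estimated correlation, while the preset correlation passed 5 and fry 2. A fit of these 2 groups alone called 1433 loci and one with sample weights 2334. Without HF_PBS 3 and 4, chosen after seeing the data for their subcortical scores, 320 loci passed, with 3 ribosomal and 2 respiratory members up and 1 insulin and 1 synaptic member down. Without the striatum-high HF 8 and HF_PBS 2, 3 and 4, which leaves 1 HF_PBS library, 0 loci passed, and with the striatum and subcortical scores as covariates 1020 passed and 56 of 80 followed genes were lost. Without HF 6 the count was 1633 and without HF_PBS 4 it was 1683. Leaving out 1 library moved the ribosomal count to 16 (HF 6), 20 (HF_PBS 3) and 15 (HF_PBS 4), the respiratory count to 12 (HF 6), 20 (HF 8) and 13 (HF_PBS 4), and the insulin count to 4 (HF 6). Of 80 called genes that were followed, 46 stayed past the test with each library left out; without HF 5, 6, 7 and 8 the losses were 18, 34, 7 and 17, and without HF_PBS 1, 2, 3 and 4 they were 10, 7, 23 and 29, at adjusted p up to 0.158. Among those lost at least once were Cd74, Gnrh1, S100a11, Dnmt1, Dnmt3a, Cdkn1a, Pdk4, Nfkbia, Tsc22d3 and Gstm1.

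HF_PBS against chow sets the diet with vehicle injections against neither. Ribosomal protein genes rose in 39 of 61 members (41 when adjusted over the list alone), with Rpl6 from 4.56 to 10.5, and fell in none. Their adjusted p was 0.0284 with fry and 8.27e-12 with the preset correlation, and adjusted p = 0.844 with an estimated correlation. Excitatory synapse genes fell in 9 of 24 (12 when adjusted over the list alone, fry 0.0495), with Camk2a from 1570 to 714 (-1.21), Shank1 from 102 to 50.0 and Shank2 from 3.08 to 0.718. Upper cortical layer markers fell in 3 of 8 (3 when adjusted over the list alone, fry 0.0495), namely Rorb (17.8 to 5.58, -1.57), Rasgrf2 (30.6 to 16.1) and Cux2 (24.5 to 12). Both lists had adjusted p = 0.844 with an estimated correlation.

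Insulin and energy sensing genes fell in 7 of 22 and rose in 2 (9 and 2 when adjusted over the list alone, fry 0.0204), with Foxo3 (17.7 to 8.26, -1.08) and Pdpk1 (32.7 to 20.1) down. Circadian clock genes fell in 7 of 16 and rose in 1 (7 and 1 when adjusted over the list alone, fry 0.0204), among them Clock (3.63 to 1.47) and Cry2 (40.2 to 26.8). Respiratory chain subunits rose in 15 of 69 and fell in 2 (15 and 2 when adjusted over the list alone), with Ndufv2 (154 to 220) up and the succinate dehydrogenase gene Sdha (140 to 106, -0.41) down. Each of these lists had adjusted p = 0.844 with an estimated correlation. Dnmt3a fell from 7.09 to 5.39 (-0.37, adjusted p = 0.00901). Dnmt1 (0.0636), Fkbp5 (0.136), Cdkn1a (0.129), Fos (0.736), Arc (0.591) and Bdnf (0.632) did not pass. Of 14 DNA methylation genes 1 rose and 5 fell (4 and 6 when adjusted over the list alone). Cholesterol genes, with 2 up and 4 down of 23 (2 and 5 when adjusted over the list alone), had a median of 0.0255 and a mean of -0.0504, which differ in sign.

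Some markers of glia and of other regions also rose, while most did not pass. Microglia markers rose in 8 of 21 (8 when adjusted over the list alone), such as Fcer1g (20.6 to 44.3, 1.01), C1qb (26.3 to 47.6) and Trem2 (7.59 to 12.9), and astrocyte markers in 5 of 18 (5 when adjusted over the list alone), such as Aqp4 (52.7 to 117) and Gfap (87.5 to 196). Thalamus and subcortical markers rose in 3 of 14, among them Tcf7l2 (2.45 to 6.01), and striatum markers rose in 2 of 16 and fell in 1 (3 up for the former and 1 up and 1 down for the latter when adjusted over the list alone). The thalamus and subcortical score was 1.62 in HF_PBS 3 and 0.859 in HF_PBS 4, and at most -0.293 in the chow libraries. Adjusted p was 0.926 for the striatum list and 0.844 for the other lists so far in this paragraph, with an estimated correlation. Oligodendrocyte and myelin genes also rose in 4 of 25 and fell in 0 (median 0.696), and olfactory bulb markers rose in 2 of 9 and fell in 1. The myelin score was 0.393, -0.443, 1.2 and 1.16 in HF_PBS 1 to 4, and at most 0.101 in the chow libraries. With 1 locus per symbol, that of the highest mean, the largest rises with groups fully apart were of the neuropeptide gene Nts (0.304 to 14.8 ± 17.8, log2 3.46, adjusted p = 0.0462), Gal, which was listed at 0 in 1 chow library and at most at 0.841 in the others against 1.85 to 37.0 (0.00469), the neuropeptide gene Tac1 (7.52 ± 3.07 to 52.8 ± 27.8, 2.61, 0.0173), Nnat (53.9 to 434 ± 367, 2.59) and the serotonin receptor gene Htr2c (3.73 to 22.4 ± 8.62, 2.40). Nts was uneven, at 1.06, 10.7, 40.8 and 6.57 in HF_PBS 1 to 4. The largest falls by this choice were of Scn1a (16.2 ± 2.53 to 1.78 ± 1.13, -3.01, adjusted p = 0.00324), Kcns1 (39.7 to 7.86, -2.63), Kcnh7 (10.3 to 1.58, -2.50), Dbf4 (24.0 ± 2.54 to 4.52 ± 2.22, -2.39, 0.00211) and Exoc8 (0.00459). Lesser loci of Pja2 (4.90) and Nlk (-4.10), among others, changed more.

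Limma called 4173 loci, 1842 higher and 2331 lower (1404 and 1592 with a symbol), with 6285 at an unadjusted p under 0.05; no list passed with an estimated correlation, 9 with the preset correlation and 7 with fry. With a block for the replicate number, which gave no sign of pairing the samples, 2331 loci were called. Without HF_PBS 3 and 4 the count was 101, with 2 ribosomal members up and 0 in the respiratory, insulin and synaptic lists. With the striatum and subcortical scores as covariates 3 loci passed, none with a symbol, and all 96 followed genes were lost, as they were without the striatum-high HF_PBS 2, 3 and 4 and HF 8, where 2 loci passed. The count was 2706 without chow 3, 2630 without chow 4 and 2013 without HF_PBS 4. The ribosomal count was 25 without chow 4 and 23 without HF_PBS 4, the insulin count 4 without HF_PBS 4, and the respiratory count 4 without chow 4, 29 without HF_PBS 2 and 3 without HF_PBS 4. Of 96 called genes followed, 60 stayed past the test with each library left out. The losses were 17, 22, 20 and 21 without chow 1 to 4, and 4, 7, 26 and 36 without HF_PBS 1 to 4, at adjusted p up to 0.138, and took in Nts, Tac1, Nnat, Htr2c, Kcns1, Rorb, Rasgrf2, Cux2, Fcer1g and C1qb.

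HF_5AzaD against chow compares the inhibitor group with rats that had neither the diet nor injections. Ribosomal protein genes rose in 28 of 61 members (40 up and 1 down when adjusted over the list alone, fry 0.029, preset 4.57e-13). Insulin and energy sensing genes fell in 7 of 22 (8 when adjusted over the list alone, fry 0.029), with Foxo3 (17.7 to 8.42, -1.08), Pik3r1 (37.7 to 24.3) and Tsc1 down, while the growth kinase gene Mtor rose from 22.9 to 32.9. Respiratory chain subunits rose in 8 of 69 and fell in 2 (8 and 2 when adjusted over the list alone), with Sdha falling from 140 to 101. Excitatory synapse genes fell in 3 of 24 (3 when adjusted over the list alone), namely Shank1, Shank2 (3.08 to 0.908) and Shank3. Microglia markers rose in 4 of 21 (8 when adjusted over the list alone), with Aif1 from 19.3 to 40.4 (1.02). All these lists had adjusted p = 0.945 with an estimated correlation. Mural and leptomeningeal markers moved with these groups: 23 of 24 were higher (median 0.853) and 1, Cspg4, rose (0 when adjusted over the list alone, preset 0.00307, adjusted p = 0.945 with an estimated correlation). HF_5AzaD 7 had a mural score of 1.33 and a subcortical score of 0.708.

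The DNA methylation machinery had 1 member up and 5 down of 14 (1 and 6 when adjusted over the list alone, fry 0.029, adjusted p = 0.945 with an estimated correlation). The merged locus Fem1a,Uhrf1 fell from 16.2 to 9.65 and Dnmt3a from 7.09 to 5.82 (-0.27, adjusted p = 0.0497), and Dnmt1 did not pass (0.0641). The Dnmt3a call ended after quantile normalization (0.0727) and median-ratio scaling (0.0577). Clock genes fell in 3 of 16 and rose in 1, the merged locus Car11,Dbp (7 and 1 when adjusted over the list alone, fry 0.029, adjusted p = 0.945 with an estimated correlation), with Clock from 3.63 to 1.28 (-1.23). The fat synthesis genes Gpam (16.4 to 10.5) and Scd1 (5.53 to 3.42) fell. With 1 locus per symbol, again that of the highest mean, the largest rises with groups fully apart were of the antigen presentation genes Cd74 (6.03 to 22.1 ± 13, log2 1.72, adjusted p = 0.0477) and RT1-Db1 (0.860 to 3.66, 1.53), Rps29 (18.4 to 75.8 ± 76.7, 1.59, but 1.00 without HF_5AzaD 7), Rtbdn (1.21 to 4.63, 1.54) and Gstm1 (46.4 ± 8.82 to 138 ± 61.9, 1.48, SE 0.3, 0.0116). The largest falls so chosen were of Scn1a (16.2 to 3.54, -2.33), Kcnh7 (10.3 to 2.03, -2.23), Sema7a (174 to 62.1, -2.04), Exoc8 (0.0102) and Ttc39a (0.0272). Ttc39a was listed at 111, 60.2, 118 and 61.9 in chow and at 0 in 3 HF_5AzaD libraries, but also at 0 in 2 HF libraries. Lesser loci, such as those of Pja2 (4.79) and Nlk (-4.08), changed more than most of these.

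Limma called 2414 loci, 1064 higher and 1350 lower (773 and 879 with a symbol), with 5277 at an unadjusted p under 0.05; no list passed with an estimated correlation, 7 with the preset correlation and 5 with fry. Sample weights gave 3760 loci, 1 locus per symbol 1498, and an adjusted p under 0.10 gave 4215. Single libraries weighed heavily: the count was 1291, 863, 697 and 705 without chow 1, 2, 3 and 4, and 399 without HF_5AzaD 7. The ribosomal count was 14, 12 and 9 without chow 2, 3 and 4, and 10 without HF_5AzaD 7. The insulin count was 2, 1, 1 and 1 without chow 1 to 4, 4 without HF_5AzaD 3 and 0 without HF_5AzaD 7. The respiratory count was 3, 1, 1 and 1 without chow 1 to 4, 2 without HF_5AzaD 3 and 0 without HF_5AzaD 7, and the synaptic count 0 without HF_5AzaD 7. Of 72 called genes followed, 16 stayed past the test with each library left out, Gstm1, Rtbdn and Exoc8 among them. The losses were 30, 40, 45 and 44 without chow 1 to 4, and 16, 24, 6 and 55 without HF_5AzaD 3, 5, 6 and 7, at adjusted p up to 0.159. With the striatum and subcortical scores as covariates 197 loci passed, and 2 ribosomal members, and 64 of the followed genes were lost.

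HF_5AzaD against HF sets the inhibitor with its injections against the diet alone. Respiratory chain subunits rose in 20 of 69 and fell in 1 (30 and 1 when adjusted over the list alone), such as Ndufa11 (98.9 to 156) and Ndufa12 (23.5 to 37.4). Ribosomal protein genes rose in 19 of 61 (33 up and 1 down when adjusted over the list alone, preset 4.03e-10). Fat synthesis genes fell in 3 of 17 (3 when adjusted over the list alone), with the acyltransferase gene Gpam (18.9 to 10.5, -0.82, adjusted p = 0.00286) and the desaturase gene Scd1 (6.92 to 3.42, -0.91, 0.00689). Cholesterol genes fell in 6 of 23 and rose in 1 (6 and 2 when adjusted over the list alone), with Lss (8 to 4.79) and Srebf2 (57.3 to 41.9) down. Insulin and energy sensing genes fell in 5 of 22 and rose in 1 (7 and 1 when adjusted over the list alone), with Tsc2 from 37.4 to 25.3. Excitatory synapse genes fell in 3 of 24 and rose in 1, Gria4 (28.7 to 39.9), and 3 and 1 when adjusted over the list alone. Each list had adjusted p = 0.782 with an estimated correlation.

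Of the loci with the highest mean of their symbol and with groups fully apart, Pcsk1n rose most (0.222 to 8.38 ± 1.05, log2 3.64, adjusted p = 0.00945), followed by the chemokine gene Ccl19 (1.25 to 9.86, 2.27), the prostaglandin synthase gene Ptgds (400 to 1890 ± 1170, 2.15), S100a11 (2.19 to 11.1, 2.02) and Cd74 (5.10 to 22.1, 1.83). The largest falls among these loci were of Gfod1 (31.2 to 8.35, -1.79), Kcnh7 (9.19 to 2.03, -1.78), the nuclear receptor gene Nr2c2 (16.6 to 4.63, -1.74, SE 0.315, 0.00784), Shank2 (4.26 ± 2.75 to 0.908 ± 0.458, -1.66, 0.00877) and Exoc8 (0.00877). Lesser loci of Pja2 (5.17) and Nlk (-3.81), among others, changed more. Mural and leptomeningeal markers moved with these groups: 22 of 24 were higher (median 1.12) and 2 rose, Slc6a13 and Vtn (1 when adjusted over the list alone, preset 0.000306, adjusted p = 0.782 with an estimated correlation). Their score was 0.0158, 0.316, 0.574 and 1.33 in HF_5AzaD 3, 5, 6 and 7 and -0.803 to -0.0378 in HF, and Ptgds was at 731, 1989, 1366 and 3468 in the same 4 HF_5AzaD libraries. Dnmt1 fell from 7.51 to 6.16 (-0.26, 0.0367, but 0.0679 after quantile normalization), and Dnmt3a (0.227) did not pass. Quantile normalization also ended the call of Ptgds (0.0906).

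Limma called 2112 loci, 980 higher and 1132 lower (756 and 658 with a symbol), with 4815 at an unadjusted p under 0.05; no list passed with an estimated correlation, 5 with the preset correlation and 0 with fry. A fit of these 2 groups alone called 27, one with a block for the replicate number 0, sample weights 1329, 1 locus per symbol 1275, and an adjusted p under 0.10 gave 3675. The count was 395 without HF 6, 1273 without HF 8, 1174 without HF_5AzaD 3 and 400 without HF_5AzaD 7. The ribosomal count was 6 without HF 6 and 9 without HF_5AzaD 7, and the respiratory count 3 without HF 6, 8 without HF 8, 5 without HF_5AzaD 3 and 4 without HF_5AzaD 7. The insulin count was 3, 0, 3 and 3 without HF 5 to 8, 2, 3 and 0 without HF_5AzaD 3, 5 and 7, and the synaptic count 1 without HF 6 or HF_5AzaD 7. Of 65 called genes followed, 17 stayed past the test with each library left out, Pcsk1n, Gfod1, Nr2c2, Shank2, Gpam and Scd1 among them. The losses were 18, 48, 6 and 24 without HF 5 to 8, and 24, 9, 7 and 48 without HF_5AzaD 3, 5, 6 and 7, at adjusted p up to 0.155. With the striatum and subcortical scores as covariates 133 loci passed, 4 ribosomal members among them, and 58 of the followed genes were lost.

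**Figure D1:**
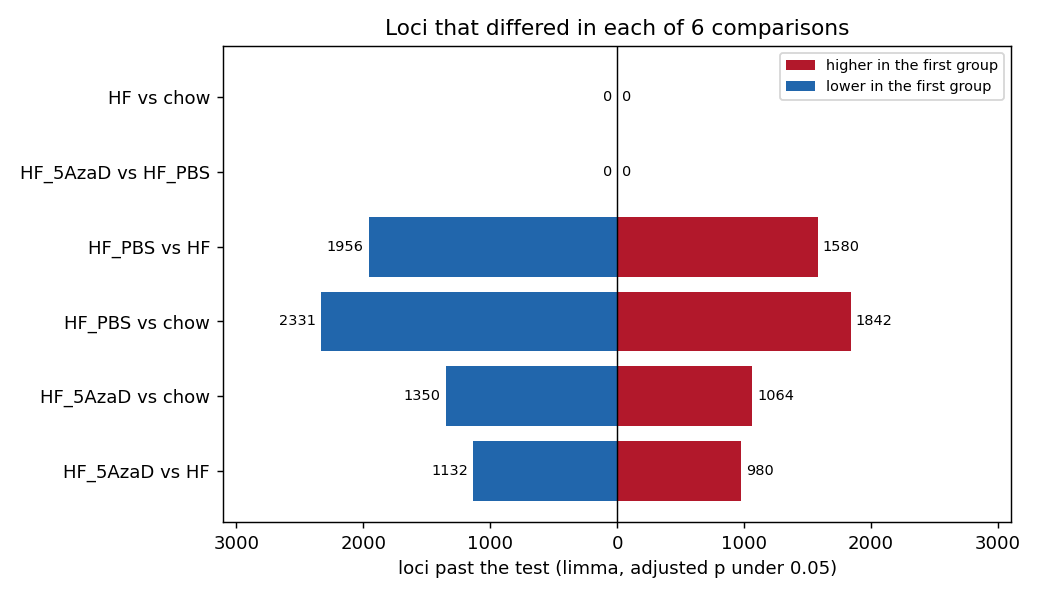
Number of loci past the test (adjusted p under 0.05) in each of the 6 comparisons, split into higher and lower. The 4 comparisons of an injected with an uninjected group hold 2112 to 4173 loci, and the other 2 hold 0.

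**Figure D2:**
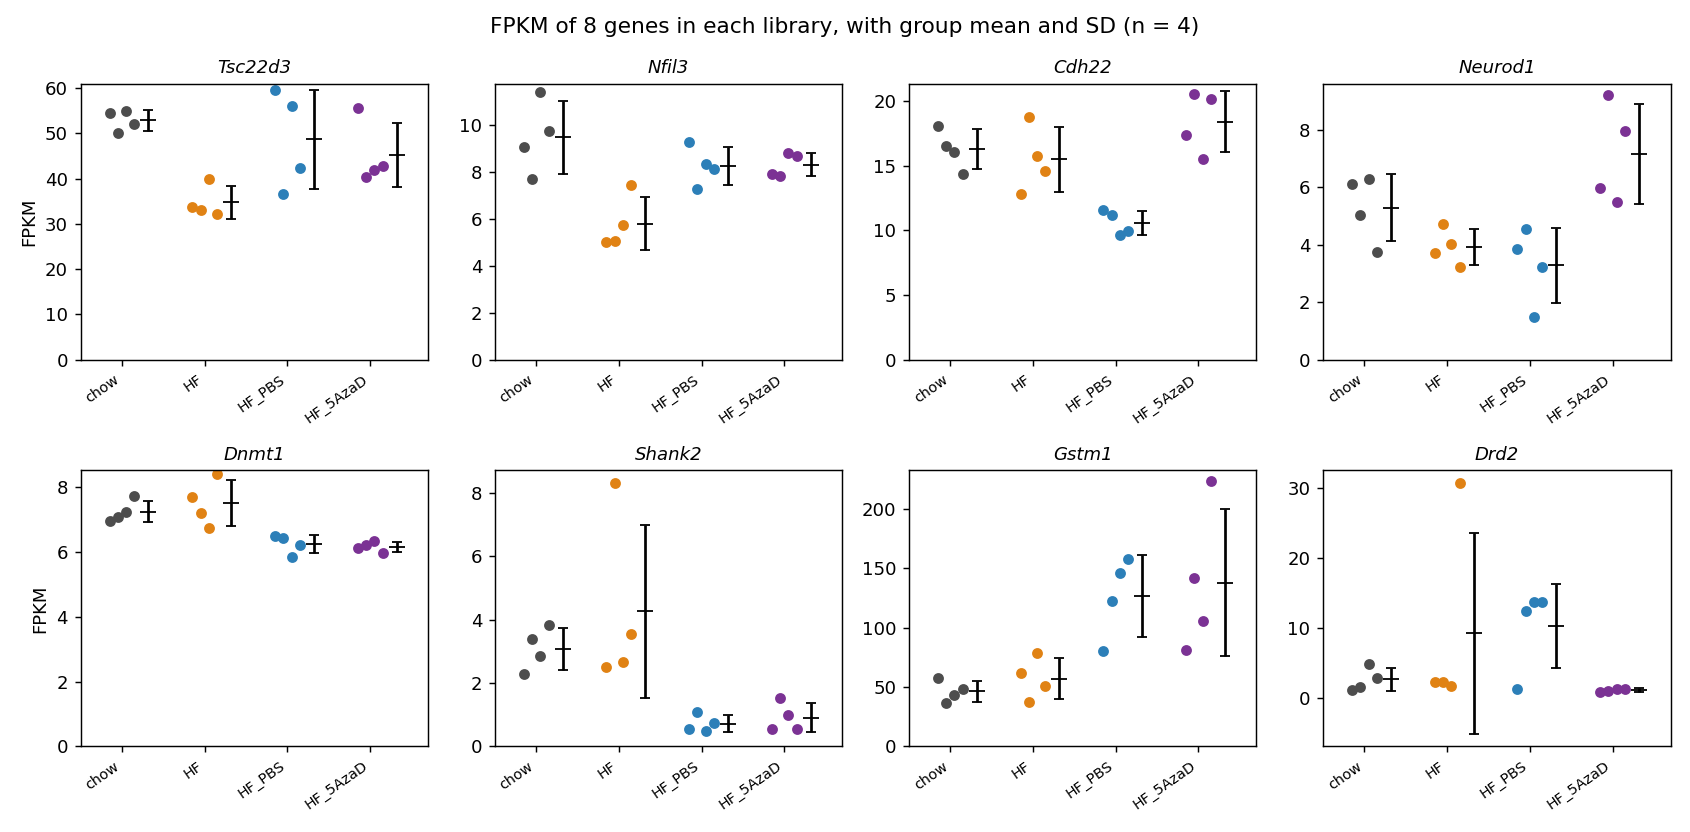
FPKM of 8 genes in each library (points) with the mean and SD of each group (n = 4). Shank2 was lower in both injected groups than in HF, while Tsc22d3, Nfil3, Cdh22 and Neurod1 show differences that did not pass the test in the diet or the inhibitor comparison.

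The genes called in injected against uninjected groups overlapped across comparisons that share no library. HF_PBS against HF and HF_5AzaD against chow shared 576 loci up and 930 down, and 1 locus went opposite ways. HF_PBS against chow and HF_5AzaD against HF shared 612 up and 806 down, with 2 opposite. All comparisons use 1 fit with a common variance per locus, so their calls are not independent and no chance level is given. The first principal component, with 35.3% of the variance, placed the 8 injected libraries at 7.95 to 60.7 and the 8 uninjected at -54.5 to -15.4. Some symbols stand for several loci, which can go opposite ways: of 48 symbols with at least 2 loci called in HF_PBS against HF, 30 had loci called both up and down.

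**Figure D3:**
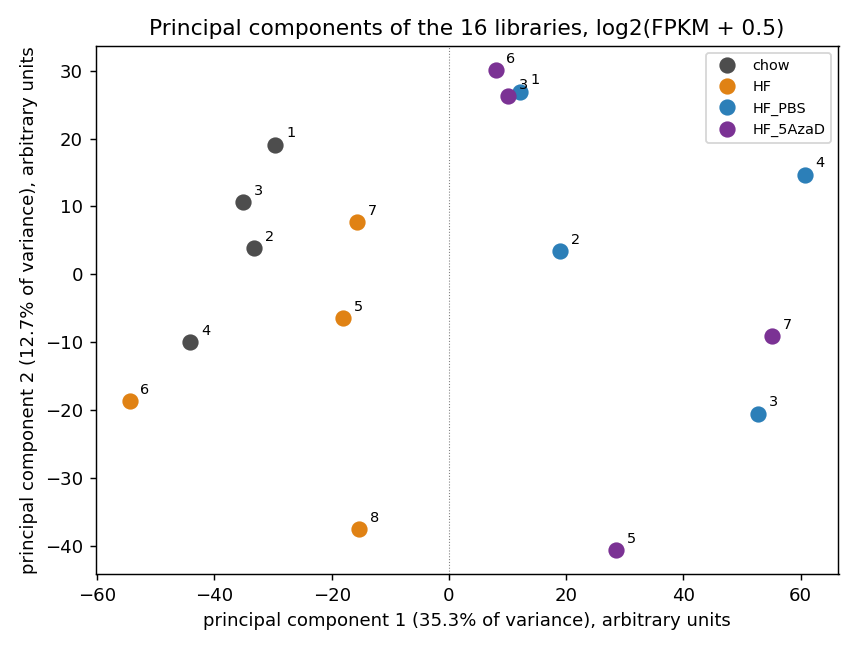
First and second principal component of the log2 values of the 14824 tested loci, with 35.3% and 12.7% of the variance, 1 point per library and 4 libraries per group. Injected libraries lie at 7.95 to 60.7 on the first component and uninjected libraries at -54.5 to -15.4.

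Scores of regional and cell type lists, the mean log2 deviation of their members from the average of the 16 libraries, varied inside groups. The striatum score was 2.16 in HF 8, 1.11 in HF_PBS 2, 0.94 in HF_PBS 3 and 1.15 in HF_PBS 4, and at most 0.194 elsewhere. The thalamus and subcortical score was highest in HF_PBS 3 (1.62), HF_PBS 4 (0.859) and HF_5AzaD 7 (0.708), and the myelin score in HF_PBS 3 (1.2) and HF_PBS 4 (1.16). The mural and leptomeningeal score was 1.35 in HF_PBS 2 and 1.33 in HF_5AzaD 7, and the hippocampus score 1.48 in HF_5AzaD 5 and 1.07 in HF_PBS 3.

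**Figure D4:**
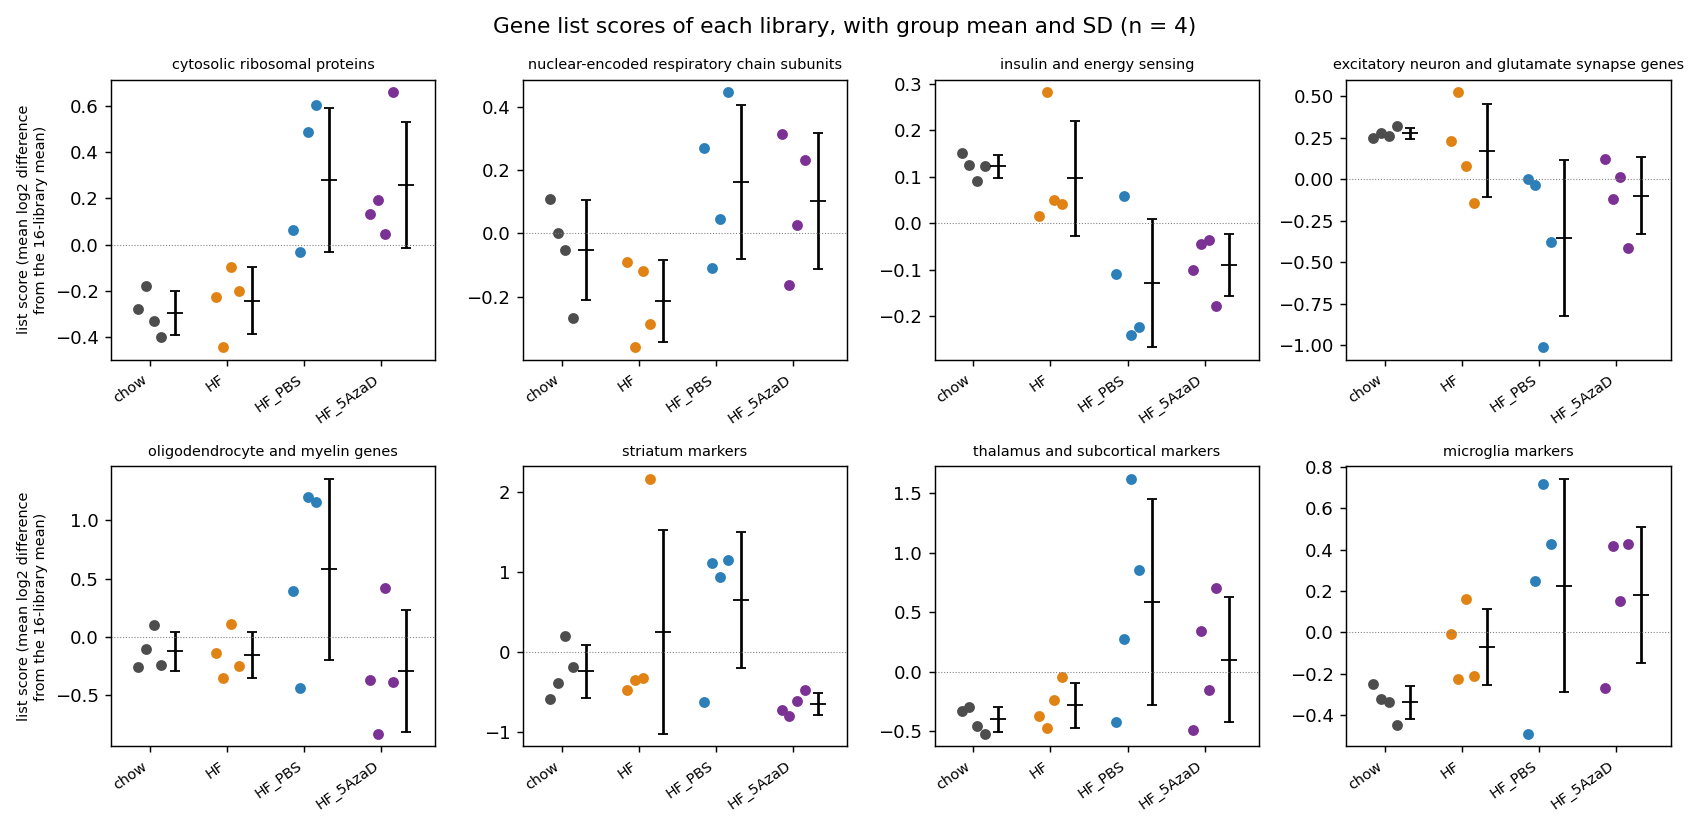
Scores of 8 gene lists in each library (points), in log2 units, grouped by the 4 groups of 4 libraries. Ribosomal protein scores lie at -0.442 to -0.0982 in uninjected and -0.0329 to 0.657 in injected libraries, and HF 8 has a striatum score of 2.16.

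Whether 5-AzaD moved genes against or along the diet was asked by correlating fold changes of HF against chow with those of HF_5AzaD against HF_PBS, which share no library. Across 14824 loci, which are not independent replicates, Pearson's r was -0.184 and Spearman's rho -0.0973. Regrouping the samples within both pairs gave r between -0.247 and 0.272 in the central 95% of regroupings, and a two-sided permutation p of 0.218 (100 regroupings, smallest possible 0.0099). Without HF_5AzaD 5 r was -0.284 with a p of 0.0198, without HF_5AzaD 6 it was -0.0708, without HF_5AzaD 3 -0.0851, without HF_PBS 3 -0.112, and it turned to 0.012 without the subcortical-high and 0.0263 without the striatum-high libraries. Whether HF and HF_PBS moved away from chow alike was asked by correlating HF against chow with HF_PBS against chow. Across genes r was 0.431 and rho 0.351. Simulated groups with no change, against a shared control also simulated, gave r = 0.482 on average. Their spread was pooled over all 16 libraries. The covariance was 0.0891 against 0.0518 simulated, and the p from the simulated covariances was 0.376 (two-sided, smallest possible 0.02). With the chow libraries split 2 and 2, so that no library was shared, r was 0.29 (0.141 to 0.405 over the splits), and without the striatum-high libraries r was 0.264. These were the 2 correlations computed.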

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

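The tests of sequencing depth, of a batch that follows the injections, of uneven dissection and of a 5-AzaD effect on striatum and myelin genes, and the covariate fits and left-out samples chosen by regional scores, were chosen only after the result was seen. Samples far from the other 3 of their group were searched in 412 groups of values; 36 held one, where chance alone gives about 1 in 20 groups, or 20.6.

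HF 8 stood out by striatal genes. Its striatum score was 2.16, Drd1 was at 44.96 FPKM (1.825 to 4.124 in the other HF samples), Drd2 at 30.66 (1.612 to 2.226), Adora2a at 59.43 (2.336 to 4.414), Six3 at 9.463 (at most 0.3508) and Tac1 at 125.5 (8.527 to 19.26). In the same sample Nts was at 22.26 (at most 3.543), Trh at 3.342 (at most 0.2578), Oxt at 1.995 (0.1273 to 0.2963), Gnb4 at 7.287 (4.036 to 4.37) and Fos at 30.18 (4.046 to 6.979). HF_PBS 1 lay below the rest of its group, with a striatum score of -0.626 (0.94 to 1.15 in the other HF_PBS samples) and Drd2 at 1.263 (12.37 to 13.73). Its values were like those of HF_5AzaD, with scores of -0.796 to -0.48 and Drd2 at 0.7412 to 1.306. The high samples of its group are therefore the unusual ones. HF_PBS 3 held hypothalamic peptide genes, with Oxt at 402.7 (0.2343 to 46.63), Trh at 30.24 (at most 4.817) and Gnrh1 at 12.28 (at most 1.09). Nts was at 17.54 in HF_5AzaD 7 (at most 1.807).

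The choroid plexus gene Ttr was at 35.46 in chow 2 (1.66 to 6.882 in the others) and at 26.15 in HF_PBS 1 (3.049 to 6.175). HF_PBS 2 held high Ptgds at 2594 (434.8 to 661.7), Ccl19 at 10.7 (1.534 to 2.413) and Nr2c2 at 6.606 (3.038 to 3.533). The ribosomal protein gene Rps29 was at 190.5 in HF_5AzaD 7 (28.81 to 42.65) and at 25.83 in HF 7 (15.5 to 16.54). Bdnf was at 9.899 in HF 5 (4.445 to 4.93), Kcnh7 at 21.53 in HF 6 (4.231 to 5.674), Caln1 at 18.91 in HF_5AzaD 5 (4.812 to 5.926), Pon2 at 45.65 in HF 7 (33.78 to 35.76), Tsc22d3 at 55.68 in HF_5AzaD 3 (40.43 to 42.8) and Agrn at 27.06 in chow 4 (21.83 to 22.37). Exoc8 was at 2.39 in HF_PBS 1 and 2.057 in HF_5AzaD 3 with the other 3 samples of each group listed at 0, and Ttc39a likewise at 65.48 in HF_PBS 4 and 0.8495 in HF_5AzaD 6. The insulin and energy sensing score was 0.282 in HF 6 and the oligodendrocyte precursor score 0.318 in HF 7.

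The first pattern weighed is the large set of loci that differ between injected and uninjected samples, 6041 in a pooled contrast of 8 against 8 (2926 higher and 3115 lower). Scaling by the authors is argued against, since 94.7% of these loci were still called in the same direction after quantile normalization. Depth did not divide the 2 kinds, since 10 of the 16 samples had read values inside the range of the other kind. The overlap comes largely from the wide uninjected range, from 30.1% of the deepest sample in HF 6 to 100% in chow 2. Whether depth affected the calls was not tested. Striatal or other subcortical tissue may account for part of it: with the striatum and subcortical scores as covariates the slope of the adjusted on the unadjusted changes was 0.784 (0.691 to 0.848 with each sample left out, where only values all above 0.75 would have argued against it), and 2417 loci were called, 2215 of them shared and in the same direction. The labels do not say which samples were prepared or sequenced together. A library or sequencing batch that follows the injections, if there was one, cannot be told apart from the injections. The median FPKM of the tested loci was 8.866 to 9.173 in injected and 9.184 to 9.51 in uninjected samples. The share of all FPKM in a single locus was 19.2% to 59% in injected samples. In uninjected samples it was 64.1% to 76.5%, except in chow 2 (37.8%) and HF 7 (14%). The cause of these differences was not tested. In this contrast 9 loci lay fully apart with at least an 8-fold change, among them Ganab (uninjected at 0 to 0.513, injected at 2.29 to 13.7) and Nlk (6.44 to 18.7 against 0 to 1.80), whose symbols also have other loci. The injections themselves, the biological difference in the design, stay open and untested, as does an exchange of the names HF and HF_PBS.

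The second pattern is the lower level of striatum and myelin genes in HF_5AzaD than in HF_PBS. Uneven dissection of striatum and white matter is a candidate explanation. Striatum markers rose and fell together between samples inside groups, with a residual correlation of 0.652 over all 16 samples, HF 8 (score 2.16) included. Genes regulated together would also do so, so this value does not tell dissection from an effect of 5-AzaD. The most abundant striatum markers Penk (270 ± 140 in HF_PBS and 99.1 ± 34.2 in HF_5AzaD) and Ppp1r1b (257 ± 116 and 130 ± 22.9) varied widely inside HF_PBS. All 16 measured striatum markers also reach a mean of 1 FPKM in chow cortex and 2 of them are on another list, as are 25 and 1 for the 25 myelin genes. An effect of 5-AzaD stays open, as 3 of the HF_PBS values, over both scores, did not lie above all 4 of HF_5AzaD.

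Other splits of the same 8 samples show how often a split without the treatment gave as many calls. In HF against chow (0 loci called, at most 2 in another split) and in HF_5AzaD against HF_PBS (0 called) the splits decide nothing about chance, since any split gives at least 0 loci and all 35 of 35 therefore count. In the latter, a split of HF_PBS 1 and 2 with HF_5AzaD 3 and 6 against the rest called 1427 loci, which points to a structure of the samples other than the treatment. Only the real split, 1 of 35, gave as many in HF_PBS against HF (3536 called, at most 46 in another split), HF_PBS against chow (4173, at most 0), HF_5AzaD against chow (2414, at most 0) and HF_5AzaD against HF (2112, at most 140). That is the smallest share these splits can give, and the 4 comparisons share samples. Mixed splits also carry the group difference into the spread, which lowers their counts. Chance is thus made less likely but not excluded. For injected against uninjected samples, 1 of 100 drawn splits, the real one, gave as many (6007 in a fit of these 2 kinds alone, at most 4 in another).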

How the results depend on the processing

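The alternatives by loci status, by symbol and by regional scores, and those for single lists and genes in the 4 comparisons with calls, were chosen only after the result was seen. Both zero counts of genes stood under every other setting: HF against chow gave 1 locus only with loci of every status kept, by construction, and 0 with any sample left out, and HF_5AzaD against HF_PBS gave 0 to 1 with 1 sample left out. Where a count moved, the cause was not tested, except that fewer samples or a block leave less to test with.

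For HF_PBS against HF (3536 loci) the count was 2334 with sample weights, 1433 with these 2 groups only, 320 without the samples high on the subcortical list, 0 without those high on the striatum list (HF_PBS then keeps 1 sample, assumed to vary like the other groups), 1020 with both scores as covariates, and 1633 to 4036 with 1 sample left out. For HF_PBS against chow (4173) it was 2331 with a replicate block, 101 and 2 without the same samples, 3 with covariates, and 2013 to 4629. For HF_5AzaD against chow (2414) it was 3760 with weights, 1498 with 1 locus per symbol (fewer tested), 197 with covariates, 4215 at an adjusted p under 0.10, and 399 to 2906. For HF_5AzaD against HF (2112) it was 1329 with weights, 27 with 2 groups only, 0 with a replicate block (3 numbers in common), 1275 with 1 locus per symbol, 133 with covariates, 3675 at an adjusted p under 0.10, and 395 to 2306. The check of same-numbered samples gave no sign that the replicate numbers pair samples, though it could miss a weak shared effect. The share of calls that went up was 44.7%, 44.1%, 44.1% and 46.4% as reported and 49.5%, 51.3%, 51.5% and 49.8% after quantile normalization. It was 34.4% and 26.7% in HF_PBS against HF and against chow without the subcortical-high samples, and 33.5% and 39.1% in HF_5AzaD against chow and against HF with covariates; all calls left in HF_PBS against chow with covariates or without the striatum-high samples went down.

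Lists passing were 0 in every comparison with the estimated correlation, and with the preset correlation 7, 10, 5, 9, 7 and 5 in the order HF against chow, HF_5AzaD against HF_PBS, HF_PBS against HF, HF_PBS against chow, HF_5AzaD against chow and HF_5AzaD against HF. Fry passed 2, 7 and 5 in HF_PBS against HF, HF_PBS against chow and HF_5AzaD against chow, and 0 in the others. Assumed correlations between members differ between these tests by construction.

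Among genes not past the test, some log2 differences changed sign. In HF against chow Dnmt1 was at -0.00628 without HF 8, which is also the setting without striatum-high samples, and with 1 sample left out ran from -0.00628 to 0.0920, Bdnf from -0.208 to 0.1499 and Fkbp5 from -0.0350 to 0.171. In HF_5AzaD against HF_PBS Fkbp5 was at -0.103 without subcortical-high and -0.136 without striatum-high samples, Fos at 0.265 and Arc at 0.193 without the latter, and with covariates Fos at 0.788, Arc at 0.612 and Dnmt1 at 0.0291. With 1 sample left out Dnmt1 ran from -0.0455 to 8.385e-05, Bdnf from -0.300 to 0.127, Fos from -0.664 to 0.0653 and Arc from -0.734 to 0.0879. Among genes that did pass the test, Fcer1g in HF_PBS against HF (-0.125) and Cyr61 in HF_PBS against chow (-0.197) turned where HF_PBS keeps 1 sample.

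The correlation of the diet and inhibitor changes turned to 0.012 without the subcortical-high and 0.0263 without the striatum-high samples, and with 1 sample left out ran from -0.284 to -0.0708, with a permutation p of 0.0198 without HF_5AzaD 5. That of HF against chow with HF_PBS against chow ran from 0.325 to 0.562 with 1 sample left out, and was 0.382 without the subcortical-high and 0.264 without the striatum-high samples. The other planned results stayed near the reported ones (238 of the results on comparisons and 560 of those on genes). For a count this means only a value within 1.5-fold, such as 2828 in place of 4173 in HF_PBS against chow without HF_PBS 3. For a gene or a correlation it means the same direction and side of the threshold. The effect of depth on these counts was not tested; the shallowest sample had 30.1% of the depth of the deepest, and simulated 1.5-fold changes were recovered in 47.8% and 40.3% of cases in the comparisons without calls.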

Other observations

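The contrast of the 8 injected with the 8 uninjected libraries used here (both groups of each kind pooled, values as mean ± SD of 8), and the genes named from it, were chosen only after the result was seen. Some genes of vascular walls and meninges were higher in injected cortex: 10 of 24 measured mural and leptomeningeal markers rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 0.901 with an estimated correlation). The smooth muscle genes Tagln (23.7 ± 7.27 FPKM uninjected and 73.8 ± 68.7 injected, log2 1.18, adjusted p = 0.0432) and Myl9 (20.5 ± 5.43 and 45.5 ± 28.7, log2 0.95, adjusted p = 0.0221) rose, as did the matrix genes Dcn (5.23 ± 2.99 and 11.2 ± 6.56, log2 0.99, adjusted p = 0.033) and Mgp (31.6 ± 11.5 and 66.9 ± 37.6, log2 0.95, adjusted p = 0.0179) and the meningeal transporter gene Slc6a13 (2.96 ± 1.15 and 6.28 ± 3.66, log2 0.86, adjusted p = 0.0197). The score of this list was 1.35 in HF_PBS 2 and 1.33 in HF_5AzaD 7, but -0.551, -0.181 and -0.213 in HF_PBS 1, 3 and 4, below chow 1 (0.388) and chow 2 (0.0737). Of 21 microglial genes 11 rose and 0 fell (13 and 0 over the list alone; adjusted p = 0.901 with an estimated correlation). They included Aif1 (21.7 ± 4.87 and 38.7 ± 12, log2 0.79, adjusted p = 0.00508), Tyrobp (14.5 ± 2.89 and 26.5 ± 9.04, log2 0.80, adjusted p = 0.00633) and the complement gene C1qb (29.1 ± 4.23 and 46.1 ± 13.1, log2 0.62, adjusted p = 0.00552). Their score ran from -0.49 (HF_PBS 1) to 0.717 (HF_PBS 3) in injected and from -0.446 to 0.16 in uninjected libraries. All these genes overlapped between the 2 kinds of libraries.

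Among 17 imprinted genes 7 rose and 1 fell (7 and 1 over the list alone; adjusted p = 0.901 with an estimated correlation). Gnas (1000 ± 115 and 1620 ± 257, log2 0.68, adjusted p = 0.000801), Ndn (119 ± 31 and 173 ± 48.7, log2 0.53, adjusted p = 0.0179), Cdkn1c (1.97 ± 0.506 and 3.78 ± 1.51, log2 0.75, adjusted p = 0.0101) and Igf2 (17.4 ± 12.8 and 56.9 ± 53.3, log2 1.51, adjusted p = 0.0383), which is also a leptomeningeal marker, were higher, and Mest (19.4 ± 3.17 and 12.9 ± 2.21, log2 -0.57, adjusted p = 0.00139) was lower. The imprinted score was 0.314, 0.661, 0.613 and 0.965 in HF_PBS 2 and 3 and HF_5AzaD 5 and 7, but -0.204, 0.0134, -0.147 and -0.251 in HF_PBS 1 and 4 and HF_5AzaD 3 and 6, inside the uninjected range of -0.46 to 0.165. Thalamus and subcortical markers rose in 5 of 14 and fell in 0 (5 and 0 over the list alone; adjusted p = 0.901 with an estimated correlation), with scores of -0.419, 0.275, 1.62 and 0.859 in HF_PBS 1 to 4 and -0.49, 0.339, -0.151 and 0.708 in HF_5AzaD 3, 5, 6 and 7. Of 20 receptor genes for serotonin, dopamine, opioids and related ligands, 0 rose and 7 fell (0 and 7 over the list alone; adjusted p = 0.901 with an estimated correlation), among them Htr6 (3.52 ± 0.911 and 1.52 ± 0.767, log2 -1.06, adjusted p = 0.00348), Htr5a (4.38 ± 0.542 and 2.72 ± 0.778, log2 -0.63, adjusted p = 0.00124) and the delta opioid receptor gene Oprd1 (4.16 ± 0.84 and 2.2 ± 1.17, log2 -0.87, adjusted p = 0.00692). Fatty acid oxidation genes moved both ways, with 8 of 23 up and 2 down (8 and 2 over the list alone; adjusted p = 0.901 with an estimated correlation): Cpt1c (31.2 ± 2.61 and 46.5 ± 7.26, log2 0.56, adjusted p = 0.000489) and Slc25a20 (13 ± 1.12 and 16.9 ± 1.96, log2 0.36, adjusted p = 0.00235) rose with no overlap between libraries, while the regulators Ppargc1a (9.15 ± 1.94 and 6.44 ± 1.35, log2 -0.47, adjusted p = 0.0139) and Ppard (14.3 ± 3.06 and 9.38 ± 1.9, log2 -0.58, adjusted p = 0.00381) fell.

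The red blood cell and germline lists were too small in expressed genes to test as groups. The locus of Hba1 and Hba2 had means of 172, 198, 188 and 372 FPKM in chow, HF, HF_PBS and HF_5AzaD and rose in HF_5AzaD against chow (log2 1.11, adjusted p = 0.0489), while its difference from HF_PBS (log2 1.10, adjusted p = 0.586) did not pass. Hbb had group means of 173, 180, 96.5 and 214. Of 18 germline genes 13 were in the data, the highest mean over all libraries was 0.488 FPKM (Sycp3), under the level needed for the test, and Mael had group means of 0.309, 0.207, 0.246 and 0.555.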
